A study of Mus musculus with 6 samples.

How the data were processed

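Bisulfite sequencing was applied to DNA of fetal mouse liver from 6 samples, 3 labelled NC and 3 labelled miR-29a-3p. Per the labels, pregnant mice on a normal diet received extracellular vesicles rich in miR-29a-3p or, as the control, vesicles rich in NC, 1 injection a day from gestation day 12.5 and 6 in total. Bisulfite turns unmethylated cytosine into uracil and leaves methylated cytosine unchanged, so the share of unconverted reads gives the methylation level. The labels also mention total RNA and an RNA library kit, but the values used here are methylation levels and no expression was analysed. The labels do not give the sex of the fetuses, or say whether fetuses of 1 group came from separate litters.

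The submitters' processing notes name FastQC, Bismark and Bowtie2, without versions, and the GRCm38 build. The region caller and its filters are not given in the sources used here. The deposited table holds 24425 lines for 14787 distinct regions, because a region is listed once for each annotation. Per the file headers and values, the authors gave the methylation level of each region as a fraction, with 1 mean for NC and 1 mean for miR-29a-3p. The authors also gave 2 signed columns treated as a score, the NC level minus the miR-29a-3p level and an area statistic for the region. Of the regions, 14786 were in CpG context and 1 in CHH context, which stayed in the counts. Each listed region had at least 5 counted sites (CpGs, except in the CHH region), a length of at least 51 bp and an absolute difference of at least 0.2. Each carried at least 1 of 10 annotations (CpG island, island shore, promoter, transcription start site, 5′ UTR, exon, intron, 3′ UTR, transcription end site or repeat), so a share of regions in a feature is not an enrichment over the genome. Levels per sample and read coverage were not used here: the depth is unknown, the spread between replicates could not be measured, and no test across samples was made.

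Coordinates are printed as the deposited table gives them, with the build left open. The notes name GRCm38, but only 56.6% of 947 exon and UTR entries fell inside a RefSeq gene of GRCm38.p6, against a median of 50.5% when positions were shifted along the chromosome. On the X chromosome the values were 41.2% and 42.2%, and the best of the shifts tried, 956 kb, gave 60.7%. A best shift is picked from many and was not tested against chance, so it does not settle the build. No position was converted and no RefSeq coordinate was used. Genes are listed by Ensembl identifier. None of the 4522 identifiers (0) could be paired with a symbol from the RefSeq table used here, so the 13 gene lists fixed before the data were examined, and the rule that named genes by symbol, were not evaluated. That rule took the regions with the largest difference in each direction, list members with a promoter region, the DNA methyltransferases and Tet enzymes, and genes with 5 or more regions. In its place, 2 identifiers per direction are given by size of difference.

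Lines were reduced to distinct coordinates, and a region was called higher or lower by the sign of the miR-29a-3p level minus the NC level. Shares of higher regions carry 95% Clopper-Pearson intervals, which cover counting error only. The 10 features, whatever their number of regions, and repeat classes or families with at least 40 regions were compared in direction by two-sided Fisher exact tests with Benjamini-Hochberg adjustment, separately for autosomes, X and Y. Regions are not independent and came from the same 6 samples, so these p-values compare regions and say nothing of the spread between animals. The comparison of X with autosomes, the repeat, methylation-level and CpG-number comparisons, the level limit of 0.4 and the limit of 20 CpGs were chosen after the data were examined. Densities per Mb use the span from the first to the last region of a chromosome. Alternatives were larger differences, more CpGs, a larger area statistic, autosomes alone, merging of regions within 1000 bp, CpG context alone and 1 feature per region.

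The comparisons were tested on simulated directions placed on the real regions, with 200 simulations. For the 2823 X regions the interval covered the planted share in 94% of simulations. For the 683 autosomal promoter regions, a planted share of 60% was found in 98%. For the 11207 autosomal regions with no planted effect, 0.70% of feature tests passed. Directions were drawn independently for each region here, so these values do not cover dependence between regions. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.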

Results

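DNA methylation was measured in fetal livers after maternal injection of extracellular vesicles rich in miR-29a-3p (3 samples) or in NC (3 samples). miR-29a-3p is a microRNA whose known targets include de novo DNA methyltransferases, and the series asked whether it affects methylation in the fetal liver. The values are the authors' group means for 14787 called regions, with no replicate error and unknown depth. Regions were short, with a median of 6 CpGs and 152 bp.

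Methylation was higher in miR-29a-3p in 7037 regions and lower in 7750. The share of higher regions was 47.6% (95% Clopper-Pearson interval 46.8% to 48.4%). Regions higher in miR-29a-3p had a median level of 0.524 in NC and 0.770 in miR-29a-3p, and regions lower in miR-29a-3p had 0.766 and 0.521. The median absolute difference was 0.229 in either direction (quartiles 0.212 and 0.261 for higher regions, 0.212 and 0.262 for lower regions). An absolute difference of at least 0.3 was found in 1648 regions, 11.1% of the total. The share moved to 50.1% on autosomes alone and to 51.8% among regions of at least 10 CpGs, so the small excess of lower regions did not hold across these settings.

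The excess of lower regions lay on the X chromosome. Of 2823 X regions, 1032 were higher and 1791 lower in miR-29a-3p, a share of 36.6% higher (34.8% to 38.4%). The 11207 autosomal regions divided into 5610 higher and 5597 lower, 50.1% higher (49.13% to 50.99%). X and autosomes differed in direction (odds ratio 0.575, two-sided Fisher exact p = 4.22e-38 over regions). Single autosomes ranged from 46.4% higher on chromosome 18 to 53.7% on chromosome 11. The X chromosome also carried more regions, 17.0 per Mb against 4.68 per Mb on autosomes, a ratio of 3.63. Lower regions reached 10.8 per Mb on X and higher regions 6.22 per Mb, against 2.34 per Mb for each direction on autosomes. The Y chromosome had 708 regions, 374 higher and 334 lower, at 7.85 per Mb. Of these, 29.8% differed by at least 0.3, against 9.69% on autosomes and 12.1% on X. Repeats overlapped 95.5% of Y regions and depth is unknown. Less precise levels on Y therefore cannot be told apart from larger changes there. A single mitochondrial region, MT 8845 to 8925 in a promoter and exon, had a level of 11.6% in NC and 32.4% in miR-29a-3p.

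**Figure D1:**
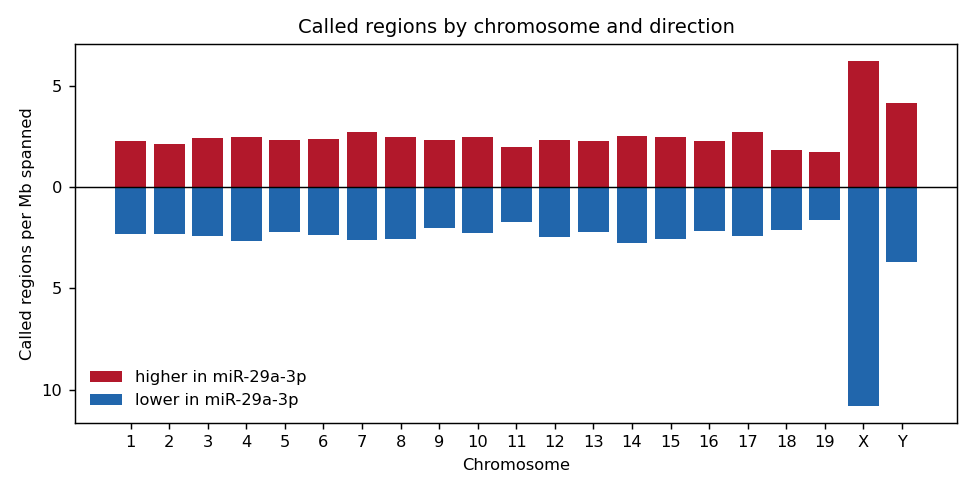
Called regions per Mb of each chromosome's span, drawn upward for regions higher in miR-29a-3p and downward for regions lower in miR-29a-3p. The X chromosome stands out with 6.22 higher and 10.8 lower regions per Mb, and autosomes together have 2.34 per Mb in each direction.

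Within the X chromosome, direction changed with the methylation level and the number of CpGs. Of 71 X regions with a mean level of both groups below 0.4, 55 were higher in miR-29a-3p (77.5%, 66.0% to 86.5%). Of 2752 X regions at or above that level, 977 were higher (35.5%, 33.7% to 37.3%; Fisher exact p = 1.50e-12 over regions). Direction on X also turned with CpG number: of 66 X regions with at least 20 CpGs, 40 were higher (60.6%, 47.8% to 72.4%; odds ratio 2.74 against X regions with fewer CpGs, Fisher exact p = 7.71e-05). On autosomes 150 of 242 such regions were higher (62.0%, 55.5% to 68.1%; Fisher exact p = 0.000200 against fewer CpGs). On Y the count was 7 of 20 (35%, 15.4% to 59.2%), and 4 of 17 (23.5%, 6.81% to 49.9%) with 15 to 19 CpGs. By level, the share fell to 27.3% among the 44 X regions with a mean level of 0.8 to 0.9. On autosomes 48.9% of 280 low-level regions and 50.1% of 10927 other regions were higher (Fisher exact p = 0.717), while the bins above 0.5 ran from 46.7% to 57.8%.

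**Figure D2:**
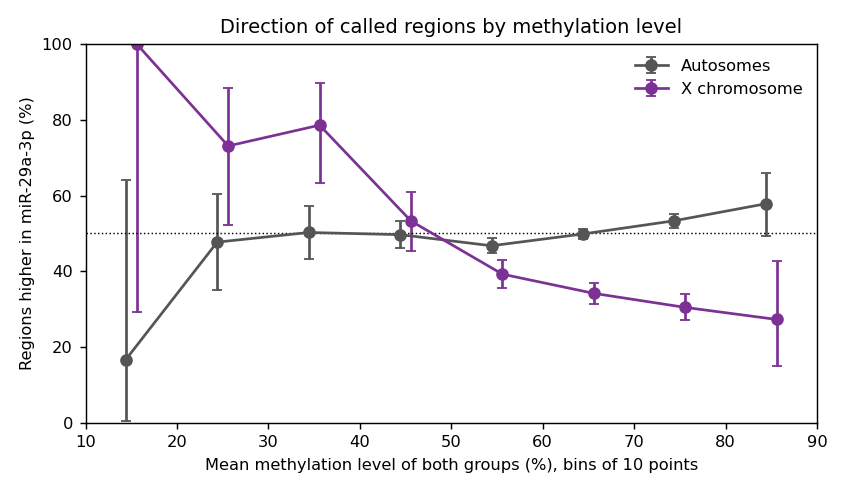
Share of called regions higher in miR-29a-3p (percent) by the mean methylation level of both groups, in bins of 10 percentage points, for autosomes and the X chromosome. Bars are 95% Clopper-Pearson intervals; the X share goes from 78.6% in the bin from 0.3 to 0.4 to 27.3% in the bin from 0.8 to 0.9, and the lowest bin holds 6 autosomal and 3 X regions.

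Gene features on autosomes carried higher and lower regions about equally often. Promoters held 339 higher and 344 lower regions, introns 2401 and 2390, exons 275 and 273, CpG islands 12 and 12, and island shores 102 and 112. For 5′ UTRs the counts were 25 and 17. None of the 10 features differed in direction from the remaining autosomal regions (0 with an adjusted p below 0.05 and 0 unadjusted, Fisher exact tests). On X, repeats were higher less often than regions outside repeats, 35.5% against 43.4% (Fisher exact test, unadjusted p = 0.00275, adjusted p = 0.0275). X promoters held 62 higher and 93 lower regions. X transcription start sites held 5 and 14, and X islands 7 and 5. X shores held 25 and 22, or 53.2% higher against 36.3% of other X regions (Fisher exact test, unadjusted p = 0.0213, adjusted p = 0.107).

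By Ensembl identifier, regions touched 4522 genes: 1860 with only higher regions, 1948 with only lower regions and 714 with both. Promoter regions touched 716 autosomal genes, 357 with only higher and 354 with only lower regions, and 153 X genes, 56 and 92. The gene with the most regions, on X, carried 42, of which 11 were higher and 31 lower. The 2 identifiers with the largest difference in each direction had it in an intron, in 1 case also annotated as promoter. In ENSMUSG00000115527 (chromosome 14, 88271749 to 88271866, an IAPEz-int repeat) the level was 21.6% in NC and 85.3% in miR-29a-3p. In ENSMUSG00000115359 (chromosome 14, 44683874 to 44683977, intron and promoter, with Lx2 and URR1B repeats) it was 29.1% and 90.7%. In ENSMUSG00000074589 (chromosome 3, 59706724 to 59709976, also IAPEz-int) it was 79.98% and 21.7%. In ENSMUSG00000109458 (chromosome 7, 68037799 to 68038282, RLTR17B_Mm and RLTR20C1_MM repeats) it was 80.4% and 25.9%. These 4 regions have 5 to 10 CpGs each.

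CpG islands, which are mostly unmethylated in normal tissue, held 39 regions, 20 higher and 19 lower. By the area statistic in the authors' deposited table, the leading higher region was an X island of 115 CpGs overlapping a promoter (161543924 to 161544690), at 15.8% in NC and 38.7% in miR-29a-3p. In the same table the leading lower region was an exonic X island of 96 CpGs (102525551 to 102526499), at 88.5% and 60.4%. A neighbouring shore and promoter region of 53 CpGs (X, 102526692 to 102527478) had 86.3% and 61.7%. On autosomes, a promoter island of 70 CpGs on chromosome 7 (59805283 to 59805533) had 48.9% and 70.6%, and an island of 76 CpGs on chromosome 10 (80733666 to 80734208) had 63.2% and 41.3%.

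**Figure D3:**
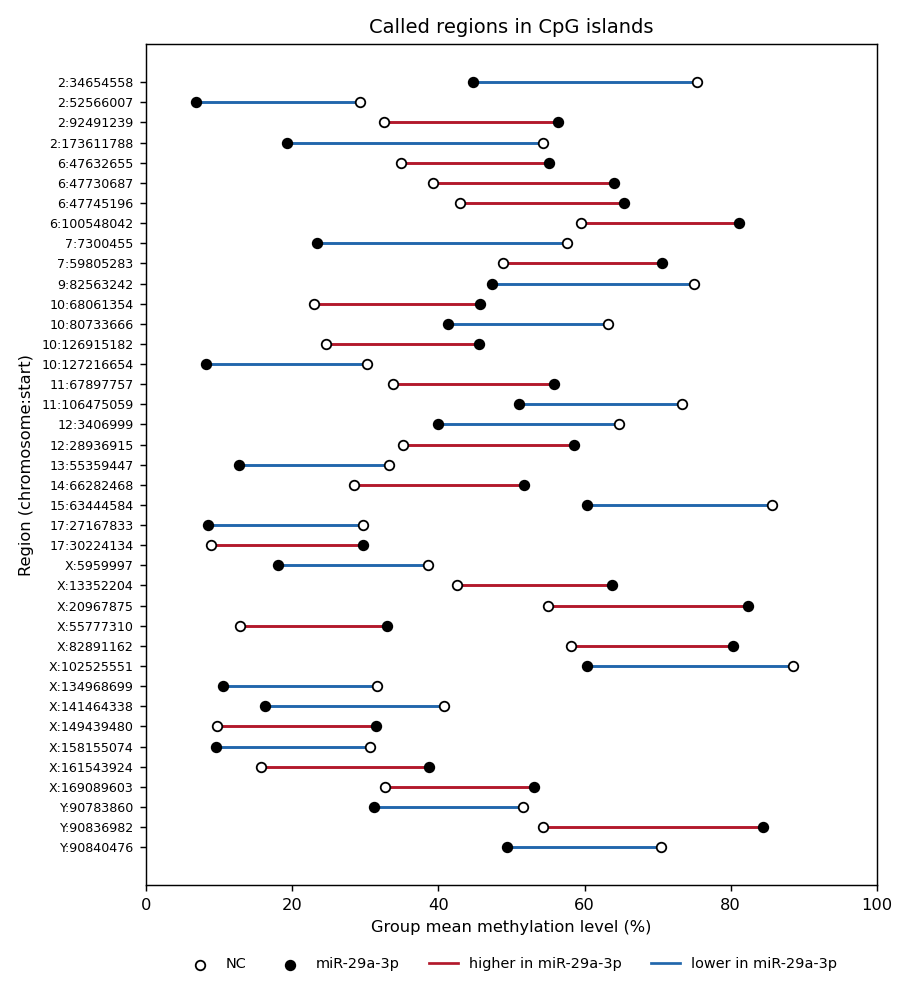
Group mean methylation level (percent) of NC (open points) and miR-29a-3p (filled points) in the 39 called regions that overlap a CpG island, listed by chromosome and start. Red lines mark the 20 regions higher in miR-29a-3p and blue lines the 19 lower ones; each point is a group mean with no error.

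Repeats overlapped 83.5% of all regions. On autosomes, LINE/L1 elements, the main active retrotransposons of the mouse, held 2517 higher and 2540 lower regions, and LTR/ERVK elements held 937 and 999. Among 14 autosomal repeat classes 0 differed in direction after adjustment and 1 before it. Among 61 families the counts were 0 and 5. Families did differ in the size of the called differences: 25.2% of 416 autosomal IAPEz-int regions differed by at least 0.3, against 10.2% of other repeat regions (Fisher exact test, adjusted p = 1.94e-15). For L1MdTf_II the values were 25.6% and 10.6% (Fisher exact test, adjusted p = 8.04e-08). SINE/Alu regions had such differences in 3.92% against 11.5% (Fisher exact test, adjusted p = 7.10e-11). Depth is unknown and mapping quality was not used here, so less precise levels in a family cannot be told apart from larger changes. All 9 X classes tested were lower in miR-29a-3p more often than higher, and 4 of them differed from other X repeat regions after adjustment (Fisher exact tests). LTR/ERVK (42.0% higher against 34.0%) and LTR/ERV1 (48.6% against 34.9%) were higher more often. SINE/B4 (24.5% against 36.1%) and SINE/B2 (24.1% against 36.0%) were higher less often. On Y, 0 features, classes and families differed in direction, before or after adjustment.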

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

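The alternatives for the X chromosome and for L1 elements, those with every annotation line for the number of regions and the share of higher regions (46.8%), those with merging or 10 CpGs for the number of regions, those other than 5 CpGs for the size of the difference, and those at 0.3 or 10 CpGs for the features were chosen after the data were examined. No paired analysis was possible because the table holds 1 mean per group; leaving out replicates, coverage minimums, means per sample and the gene lists were not run for the same reason or for want of symbols. Requiring a difference of 0.2 or 5 CpGs removed no region and tests nothing. The number of regions was 1648 at a difference of at least 0.3, 2496 at 10 CpGs or more and 24425 with every annotation line counted. The share of higher regions was 48.5% at a difference of at least 0.3, 49.4% above the median area statistic, 51.8% at 10 CpGs or more and 50.1% on autosomes alone; leaving out X removes its excess of lower regions, and for the other settings the cause was not tested. The X share was 38.4% at 0.3, 39.0% above the median area statistic, 42.5% at 10 CpGs or more and 43.4% outside repeats. At 20 CpGs or more it was 60.6% (47.8% to 72.4%), past 50% but with an interval that includes it. The cause of these shifts was not tested. The median absolute difference was 0.268 on Y alone. The number of autosomal features differing in direction stayed at 0 in each of its alternatives. The share of higher autosomal L1 regions was 49.8% (48.4% to 51.2%) at 5 CpGs or more, an even split that was counted as reversed, and 54.9% at 10 or more. Leaving aside 7 settings that removed nothing, 29 alternatives left 14 values in place, moved 11 and reversed 4. Reversed means only that the share fell on the other side of 50%, whether or not its interval includes 50%. With depth unknown, no limit from depth could be set.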

Other observations

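All tests in this part were chosen after the result was seen. CpG-rich regions of L1 elements were mostly higher in miR-29a-3p. Of 99 autosomal L1 regions with at least 20 CpGs, 71 were higher (71.7%, Clopper-Pearson interval 61.8% to 80.3%), with a median level of 60.4% in NC and 79.3% in miR-29a-3p, against 49.1% of the 4432 with 5 to 9 CpGs. The families L1MdTf_II (25 of 33), L1MdA_I (16 of 21), L1MdTf_I (15 of 21) and L1MdGf_I (8 of 10) were mostly higher, and L1MdTf_III and L1MdA_II divided evenly (3 of 6 each). Other autosomal regions of that CpG number leaned the same way less far, 79 of 143 higher (55.2%; Fisher exact p = 0.0106 for L1 against these), with LTR/ERVK at 43 of 79 and LTR/ERV1 at 10 of 16. The limit of 20 CpGs was picked after 6 limits had been looked at in 3 chromosome classes, 18 combinations in all, and after scans of 10 features, 14 repeat classes and 61 families. With 15, 25 or 30 CpGs as the limit the autosomal share was 65.7%, 75% and 70.8%, and with 10 it was 54.9%. On Y, 4 of 7 were higher. The 3 repeat classes with at least 10 such regions were each compared with regions of the same class with fewer CpGs. L1 passed adjustment and LTR/ERVK and LTR/ERV1 did not (L1 adjusted p = 2.89e-05, Fisher exact test over regions, not corrected for the choice of limit).

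For this L1 pattern, independent chance at single regions was tested by permuting directions within autosomes, X and Y 10000 times. Each time the largest absolute z, a standardised difference in the share higher, was taken over 204 sets of regions of the kinds scanned. The autosomal L1 regions of at least 20 CpGs had a z of 4.41, and 10 permutations had a largest z as large (permutation p = 0.00110). Leaving out any 1 autosome kept the share at 69.6% or more. These values argue against independent chance at single regions and against a few loci on 1 chromosome. L1 regions on X, seen in the same look and so no independent check, had shares of 37.9%, 52%, 68%, 60% and 66.7% higher with at least 10, 15, 20, 25 and 30 CpGs (Fisher exact p = 0.243, 0.00918, 0.000880, 0.0511 and 0.189 against fewer). Reads shared between near-identical copies cannot be told apart from a real difference, since 83.8% of the 99 regions lie in elements annotated close to full length and mapping quality was not used here. A difference between animals common to many L1 copies, by chance or by treatment, may equally give this pattern and was not tested.

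X regions were mostly lower in miR-29a-3p, and denser than on autosomes. Read-depth noise of equal size in both groups has no direction, and the share higher was 36.6% (34.8% to 38.4%) on X, which argues against it as the cause of the tilt but not of the density; unequal depth on X between the groups was not tested. A candidate explanation is a different sex makeup of the groups, with more females in miR-29a-3p, since an inactive X has methylated islands and a less methylated remainder. It needs low-level X regions to be mostly higher, and 77.5% were. It also needs X islands to be so, and 7 of 12 were (58.3%, 27.7% to 84.8%). With shores the count was 27 of 53 (50.9%, 36.8% to 64.9%, against 36.3% elsewhere on X, Fisher exact p = 0.0311). These intervals include 50% and do not decide. The lower island with 88.5% in NC falls under opposed expectations, as an island and as a high-level region. It is counted among the 12. The gene was not identified there or at the neighbouring start-site region, with 86.3% in NC and 61.7% in miR-29a-3p. Which expectation applies to these regions is therefore unknown, and they do not decide. The other lower X islands were low-level, where the explanation expects a higher value. Their levels in NC and miR-29a-3p were 38.6% and 18.1% (start 5959997) and 31.6% and 10.5% (134968699). Those at 141464338 had 40.8% and 16.2%, and those at 158155074 had 30.6% and 9.59%. The labels do not give sex, so a different sex makeup cannot be told apart from an effect of the vesicles on X, which was not tested.

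Autosomal regions divided evenly between directions. If they were independent chance differences at single regions, neighbours would agree in direction no more often than unrelated regions. Of 1212 pairs of neighbours 1000 to 20000 bp apart, 50.7% agreed (47.9% to 53.6%), against 50% for independent directions. In simulations where all regions of a 100 kb block shared a direction, 95.2% agreed, and weaker sharing was not simulated. Pairs 1000 to 5000 bp apart agreed in 54.1% (49.0% to 59.1%), and those 5000 to 20000 bp apart in 49.1% (45.7% to 52.6%). Chance at many of these regions would give the 50.7%, but so could local differences at single regions. The called regions alone cannot separate them. The even total also covers tilts. The share higher was 46.7% (44.8% to 48.7%) at mean levels of 0.5 to 0.6 and 53.3% (51.4% to 55.2%) at 0.7 to 0.8. Other level bins had intervals that include 50%. With at least 10 CpGs the share was 54.4% (52.1% to 56.7%). The comparison of neighbours does not address these tilts, and their cause was not tested.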
